A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

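RNA of 8 yeast samples (wild type 2, ESA1 sup2- 3, esa1 sup2- 3) was prepared with hot phenol and labelled with biotin for Affymetrix arrays, per the labels' protocols. The deposited values are probe-set intensity values on a linear scale. The authors made them with MAS5 in GCOS, per the submitters' processing notes, and versions are not given in the sources used here. The mean of each deposited array without the lowest and highest 2% of probe sets was close to 500.2 on every array (500.2 to 500.3), so the arrays had been scaled to a common mean before deposit. The instrument records of each array, deposited by the authors, were used for the fluidics station alone, which was 1 for the wild type, 3 for the single mutant and 2 for the double mutant.

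The value table held 10928 probe sets. The platform annotation and the RefSeq gene table gave 5498 probe sets of 1 S. cerevisiae gene (5449 genes), 1746 of genes outside that table, 1 listed with several genes and 3470 with no gene listed. There were also 166 control and 47 reporter probe sets. In 12 cases the symbol was updated. No array build is named, so no coordinates are printed, and the gene table served for names, chromosomes and distance from a chromosome's outermost annotated genes.

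Signals were taken as log2(signal + 121), where 120.909 is the 10th percentile of S. cerevisiae signals, with no further normalization, and probe sets in the lowest 20% of mean values were left out. A log2 fold change is on this scale and understates the change of dim genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) in 1 fit of all 8 arrays, and probe sets were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists and chromosomes were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data, for sets of at least 5 measured genes. No list or region call in any comparison held with the estimated correlation. The 40 lists, the tests and most alternatives were fixed before the data were examined. Of their 1219 symbols, 4 were not matched. Where a gene had several probe sets (26 genes) the brightest represented it, and 1 such gene had probe sets called in opposite directions in each comparison with the double mutant. Figures were drawn with matplotlib 3.10.9.

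Where a gene was below background on every array of a strain, its fold is a lower bound. Background was the 99th percentile, per array, of probe sets whose gene is outside the S. cerevisiae table, and the bright strain's mean log2 signal was set against that of the dim strain with signals raised to the bound. Of S. cerevisiae probe sets, 97.6% to 99.3% per array lay above it. Named genes are ESA1, the 8 largest increases and 8 largest decreases among called genes with arrays that did not overlap, and for each called list its 3 members with the smallest unadjusted p in the list's direction. Others are named as chosen after their values were seen.

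The steps were tested on simulated arrays built from the real means and spreads of 4398 probe sets, with 50 changed per fold size. In the simulated ESA1 sup2- against wild type comparison, 14% of 1.2-fold, 92% of 1.5-fold and 100% of 2-fold changes were recovered. For esa1 sup2- against ESA1 sup2- these were 16%, 92% and 98%, and for esa1 sup2- against wild type 12%, 86% and 98%. Among unchanged probe sets 16, 8 and 11 were called in these simulated comparisons, in that order. Far fewer probe sets were changed there than were called in the data, and their spread was simulated as independent between probe sets. These rates therefore check the steps and may not carry over to the real comparisons. Alternatives were other pseudocounts, quantile normalization, median centring, other filters, other variance models, the replicate number as a block, and each array left out in turn. Scaling on control probe sets and leaving out probe sets shared between genes were added after seeing the data, and the labels do not state that control RNA was added.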

Results

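Gene expression was measured in saturated overnight cultures of the yeast Saccharomyces cerevisiae with Affymetrix arrays, on which each gene is read by a set of short probes whose brightness is summarised as 1 signal. ESA1 encodes an essential histone acetyltransferase, the catalytic subunit of the NuA4 complex, and the study compared strains that contain ESA1 or a suppressor that bypasses the need for it. The wild type had 2 arrays. The single mutant (ESA1 sup2-), which keeps ESA1 and carries the mutation named SUP2 in the labels, had 3 arrays, and the double mutant (esa1 sup2-) had 3. The labels do not say which gene SUP2 is. Cultures of 10 mL were grown at 30 °C in rich medium with 2% glucose, and 5 µg of total RNA was used per array. Of 5498 probe sets for single S. cerevisiae genes, 4398 (4372 genes) remained after the dimmest 20% were left out. The number of arrays limits the precision of every value. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

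ESA1 (YOR244W, chromosome XV), the gene the strains differ in, was read first. Its signal was 1216 and 1067 on the wild-type arrays and 819, 894 and 877 in the single mutant. In the double mutant it was 1.19, 3.34 and 0.27, below the background bound of 11.3 to 12.4 on those arrays. The double mutant was at least 73.3-fold lower than the single mutant (limma adjusted p = 6.2e-09) and at least 96.8-fold lower than the wild type (limma adjusted p = 1.3e-08). In the single mutant ESA1 was lower than in the wild type by a log2 fold change of -0.36 (SE 0.08, limma adjusted p = 4.9e-03). That difference was not called without wild-type replicate 1 (log2 fold change -0.27, limma adjusted p = 0.060) or with arrays scaled on the poly-A control probe sets (log2 fold change -0.31). Over its 19 alternatives the limma adjusted p ran from 1.9e-03 to 0.205.

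**Figure D1:**
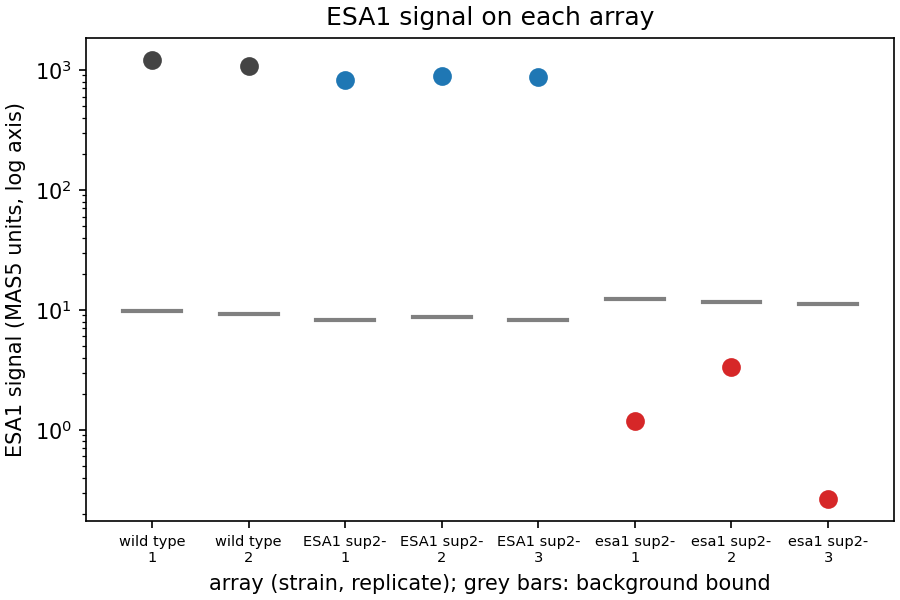
ESA1 signal in MAS5 units on a log axis for each of the 8 arrays, by strain and replicate, with grey bars at each array's background bound. The 5 arrays of strains with ESA1 lie between 819 and 1216, and the 3 double-mutant arrays lie below their bounds.

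The comparison of the single mutant with the wild type asks what accompanied the suppressor mutation while ESA1 was present. Some genes of meiosis were among the largest increases, while the meiotic list was not called (5 of 16 measured genes higher and 4 lower, 5 and 4 adjusted over the list alone, camera adjusted p = 0.72). DMC1, the meiotic recombinase, had a signal of 216 ± 5.32 (SD, n = 2) in the wild type and 2617 ± 111 (SD, n = 3) in the single mutant. Its log2 fold change was 3.02 (SE 0.07, limma adjusted p = 1.2e-07). SLZ1, a sporulation gene, rose by 2.43 (SE 0.11) and IME2, a kinase that promotes meiosis, by 2.20 (SE 0.11). FIT3, a cell wall protein of iron uptake, rose by 2.09, and ZRT1, the high-affinity zinc transporter, by 2.00. ANB1, a translation factor of low-oxygen cells, rose by 2.19 (SE 0.45) and TIR3, a cell wall protein of such cells, by 2.03 (SE 0.53). The single-mutant signals of both spread widely, at 1026 ± 586 for ANB1 and 1031 ± 688 for TIR3 (SD, n = 3), and replicate 2 of that strain stood apart from replicates 1 and 3 over all probe sets (SD of log2 differences 0.210 and 0.206, against 0.0900 between the others). TIR3 was not called without wild-type replicate 1 (limma adjusted p = 0.061) or replicate 2 (limma adjusted p = 0.069, against 5.7e-06 to 0.069 over its alternatives other than poly-A control scaling). YNL033W, read by a probe set shared with other genes, rose by 2.00.

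The largest decrease in the single mutant was that of SPS100, a spore wall gene, from 5962 ± 495 (SD, n = 2) to 337 ± 59.4 (SD, n = 3). Its log2 fold change was -3.74 (SE 0.14, limma adjusted p = 2.3e-06). The spore aquaporin gene AQY1 had a log2 fold change of -3.21 (SE 0.14), NCA3 of -2.98 (SE 0.32) and CTT1, the cytosolic catalase, of -2.49 (SE 0.20). BNA1, an enzyme of NAD synthesis from tryptophan, was at -2.15 (SE 0.35). COS2, YHR054C and THI13 were at -3.51, -2.26 and -2.17, each read by a probe set shared between related genes.

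Genes for making ribosomes rose together in the single mutant. Of 83 measured ribosome biogenesis genes, 75 were called higher and none lower (77 higher adjusted over the list alone). Their median log2 fold change was 0.68 (camera adjusted p = 3.7e-19, adjusted p = 0.25 with an estimated correlation). HAS1, a helicase of ribosome assembly, rose from 261 ± 3.52 (SD, n = 2) to 900 ± 34.6 (SD, n = 3), and RRP1 and PWP1 rose by 1.51 and 1.26 on the log2 scale. Of 128 genes of cytosolic ribosomal proteins, 106 were higher and none lower (111 higher adjusted over the list alone). The median was 0.39 (camera adjusted p = 2.4e-16, adjusted p = 0.76 with an estimated correlation), with RPL9A at 1.26 and RPS22A at 1.13. Subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, were higher in 17 of 19 cases (17 adjusted over the list alone). Their median was 0.71 (camera adjusted p = 1.4e-06, adjusted p = 0.25 with an estimated correlation), and RPC19 rose by 1.14.

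Cell cycle and phospholipid genes rose as well. Of 29 G1/S genes, 22 were higher and none lower (22 adjusted over the list alone). The median was 0.58 (camera adjusted p = 1.4e-06, adjusted p = 0.68 with an estimated correlation), with the DNA ligase gene CDC9 at 0.58 and the cyclin gene CLB5 at 0.59. Of 17 G2/M genes, 12 were higher and none lower (12 adjusted over the list alone). Here the median was 0.67 (camera adjusted p = 3.4e-04, adjusted p = 0.68 with an estimated correlation), with the kinase gene DBF2 at 1.03 and CDC20, an activator of the anaphase-promoting complex, at 1.01. In the inositol-choline regulon of phospholipid synthesis 12 of 19 genes were higher and none lower (12 adjusted over the list alone, median 0.45). This call had a camera adjusted p of 1.2e-03 (adjusted p = 0.25 with an estimated correlation). INO1, which makes inositol phosphate, rose from 2420 ± 42.4 (SD, n = 2) to 7229 ± 173 (SD, n = 3), and the phospholipid gene EPT1 from 135 to 542. Of 12 daughter-cell genes, 6 were higher and none lower (6 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.68 with an estimated correlation). That call ended without either wild-type array, without single-mutant replicate 1 or 2, with scaling on either kind of control probe sets, with a pseudocount of 1 and without the dimmest 50% of probe sets. Over its 18 alternatives the camera adjusted p ran from 0.015 to 0.211.

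Stress and stationary-phase genes fell in the single mutant. Of 57 targets of the general stress factors Msn2 and Msn4, 31 were lower and 3 higher (31 and 3 adjusted over the list alone). Their median was -0.41 (camera adjusted p = 1.4e-06, adjusted p = 0.68 with an estimated correlation). HXT5, a hexose transporter of slow growth, was at -1.48 and XBP1, a stress-induced repressor, at -0.97. Of 22 stationary-phase genes, 10 were lower and none higher (10 adjusted over the list alone, median -0.26). This list had a camera adjusted p of 1.2e-03 (adjusted p = 0.45 with an estimated correlation), with the proton pump gene PMA2 at -2.01 and HBT1 at -1.74. Of 30 protein folding genes, 14 were lower and 3 higher (14 and 5 adjusted over the list alone, median -0.24). The Hsp70 genes SSA3 and SSA4 were at -1.37 and -1.22. The folding call (camera adjusted p = 0.017, adjusted p = 0.85 with an estimated correlation) ended without wild-type replicate 2 (camera adjusted p = 0.066, against 2.2e-03 to 0.066 over its 18 alternatives). Of 39 genes of the respiratory chain and ATP synthase, 12 were lower and none higher (7 lower adjusted over the list alone). The median was -0.24 (camera adjusted p = 8.0e-04, adjusted p = 0.85 with an estimated correlation), with ATP3 at -0.48 and INH1 at -0.54. Neither gene was called with poly-A control scaling (limma adjusted p of 2.5e-04 to 0.108 for ATP3 and 3.2e-04 to 0.060 for INH1 over 21 alternatives each).

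In the single mutant against the wild type, limma called 2227 of 4398 probe sets (1253 higher, 974 lower). Of these, 141 rose and 61 fell at least 2-fold, and arrays of the groups did not overlap for 77.8% of probe sets, where chance gives 20%. The count was 1436 without wild-type replicate 1, 1406 without replicate 2, 1228 with poly-A control scaling, in which limma gave probe sets of like signal nearly 1 shared spread, and 1377 without the dimmest 50% of probe sets. The share of calls that were higher was 56.3%, against 69.4% with scaling on either kind of control probe sets, 51.0% with quantile normalization and 48.0% with median centring. Fluidics station differed between all 3 strains, so batch and group cannot be told apart in any comparison.

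**Figure D2:**
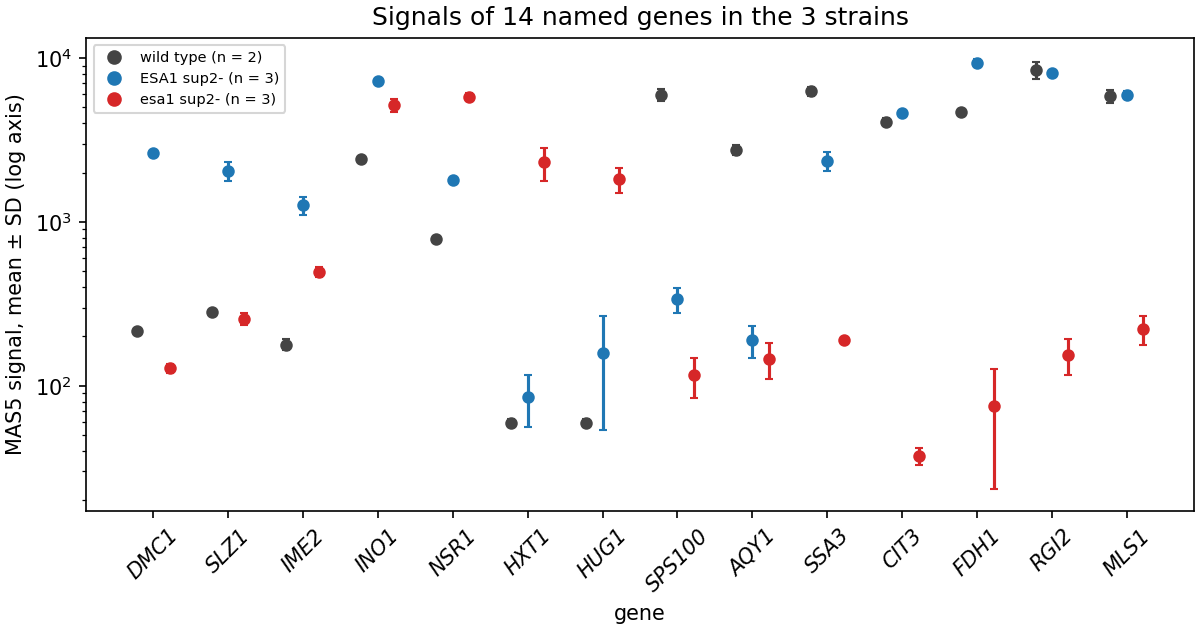
MAS5 signals on a log axis for named genes, with points for strain means and bars for SD (wild type n = 2, each mutant n = 3). DMC1 is at 216 in the wild type, 2617 in the single mutant and 128 in the double mutant, while FDH1 is at 9305 in the single mutant and 75.2 in the double mutant.

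The comparison of the double with the single mutant asks what accompanied the absence of ESA1 in strains that both carry the suppressor mutation. Genes for using carbon sources other than sugar fell most. FDH1, a formate dehydrogenase, went from 9305 ± 537 (SD, n = 3) to 75.2 ± 51.9 (SD, n = 3), a log2 fold change of -5.62 (SE 0.16, limma adjusted p = 1.9e-08). RGI2, a gene of respiratory growth, was at -4.92 (SE 0.11), and CIT3 and PDH1, which act in mitochondrial propionate breakdown, were at -4.91 (SE 0.07) and -4.34 (SE 0.09). The acetate transporter gene ADY2 was at -4.24, MLS1, the malate synthase of the glyoxylate cycle, at -4.15, the peroxisomal catalase gene CTA1 at -4.10 and the thiolase gene POT1 at -4.06. Of 21 genes of gluconeogenesis and the glyoxylate cycle, 20 were lower and none higher (20 adjusted over the list alone). Their median log2 fold change was -3.004 (camera adjusted p = 4.3e-10, adjusted p = 0.31 with an estimated correlation). Of 20 fatty acid beta-oxidation genes, 19 were lower and 1 higher (19 and 1 adjusted over the list alone). The median was -2.50 (camera adjusted p = 1.8e-09, adjusted p = 0.13 with an estimated correlation).

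Respiratory, stationary-phase and nitrogen genes also fell in the double mutant. Of 18 tricarboxylic acid cycle genes, 17 were lower and none higher (18 adjusted over the list alone). The median was -0.94 (camera adjusted p = 3.2e-07, adjusted p = 0.32 with an estimated correlation). SDH2 was at -1.72 and CIT2, which is also on the gluconeogenesis and glyoxylate cycle list, at -2.20. Of 39 genes of the respiratory chain and ATP synthase, 27 were lower and 2 higher (28 and 2 adjusted over the list alone, median -0.34). The camera adjusted p was 4.2e-04 (adjusted p = 0.50 with an estimated correlation), and the NADH dehydrogenase gene NDE2 was at -3.10. Of 22 stationary-phase genes, 16 were lower and none higher (16 adjusted over the list alone, median -1.05). This list had a camera adjusted p of 2.1e-04 (adjusted p = 0.31 with an estimated correlation), with SPG1 at -3.84 and SIP18 at -3.75. Targets of nitrogen catabolite repression were lower in 14 of 19 cases and higher in 2 (14 and 2 adjusted over the list alone, median -0.90). Their camera adjusted p was 7.2e-04 (adjusted p = 0.40 with an estimated correlation), with PUT1, of proline breakdown, at -2.41. Metabolic genes controlled by the repressor Ume6 were lower in 10 of 15 cases and higher in none (10 adjusted over the list alone, median -0.73). The camera adjusted p was 8.8e-04 (adjusted p = 0.48 with an estimated correlation), and among them were POT1, PUT1 and ACS1, which also belong to the carbon and nitrogen lists.

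Meiotic and G2/M genes were lower in the double than in the single mutant. Of 16 measured meiotic and sporulation genes, 14 were lower and none higher (14 adjusted over the list alone). The median was -0.89 (camera adjusted p = 4.1e-06, adjusted p = 0.13 with an estimated correlation). DMC1 was at -3.46 (SE 0.07) with a signal of 128 ± 8.82 (SD, n = 3), while ADY2 and CRC1, also on this list, are transporters of acetate and carnitine. Of 17 G2/M genes, 12 were lower and 1 higher (13 and 2 adjusted over the list alone), with BUD4 at -0.80 and a median of -0.42. The G2/M call (camera adjusted p = 0.014, adjusted p = 0.50 with an estimated correlation) ended with quantile normalization and with poly-A control scaling (camera adjusted p of 6.1e-03 to 0.148 over its 17 alternatives).

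Genes for making ribosomes rose in the double mutant, and transporter genes were among the largest single increases. HXT1, a low-affinity glucose transporter, went from 85.8 ± 29.7 (SD, n = 3) to 2310 ± 525 (SD, n = 3). Its log2 fold change was 3.54 (SE 0.16, limma adjusted p = 3.2e-07), and HXT2, another hexose transporter, rose by 2.76 (SE 0.27). The list of hexose transporters was not called, with 5 of 7 measured genes higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.13), except with poly-A control scaling (4.8e-05 to 0.829 over 18 alternatives). HUG1, a gene of the DNA damage response, rose by 2.87 (SE 0.27), the cell wall gene TIR1 by 2.74 (SE 0.30), the RNA helicase gene DBP2 by 2.56 (SE 0.12) and the aldehyde reductase gene ARI1 by 2.52 (SE 0.15). INA1 and YNR014W rose by 3.06 and 2.70. Of 128 cytosolic ribosomal protein genes, 122 were higher and none lower (123 adjusted over the list alone). The median was 0.37 (camera adjusted p = 3.1e-16, adjusted p = 0.48 with an estimated correlation). Of 70 genes of mitochondrial ribosomal proteins, 55 were higher and 2 lower (56 and 2 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 4.1e-09, adjusted p = 0.50 with an estimated correlation), with MRPL27 at 1.02. Ribosome biogenesis genes were higher in 54 of 83 cases and lower in 2 (54 and 2 adjusted over the list alone). Here the median was 0.36 (camera adjusted p = 1.8e-08, adjusted p = 0.40 with an estimated correlation), and NSR1, a nucleolar protein gene, rose by 1.61. Polymerase I and III subunits were higher in 13 of 19 cases and lower in 1 (13 and 1 adjusted over the list alone, median 0.55). Camera gave these subunits an adjusted p of 2.2e-03 (adjusted p = 0.39 with an estimated correlation).

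Amino acid, ergosterol, glycolysis and cell wall lists also rose in the double against the single mutant. Amino acid synthesis genes were higher in 25 of 46 cases and lower in 4 (25 and 4 adjusted over the list alone, median 0.35). This list had a camera adjusted p of 7.2e-04 (adjusted p = 0.50 with an estimated correlation), and HIS1 rose by 2.09. Ergosterol synthesis genes were higher in 17 of 26 cases and lower in 3 (17 and 3 adjusted over the list alone, median 0.35). Camera gave this list an adjusted p of 8.8e-04 (adjusted p = 0.40 with an estimated correlation), and ERG25 rose by 1.23. Glycolysis and fermentation genes were higher in 16 of 23 cases and lower in 3 (17 and 3 adjusted over the list alone, median 0.32), with the hexokinase gene HXK2 at 1.15. That call (camera adjusted p = 8.8e-04, adjusted p = 0.48 with an estimated correlation) ended with quantile normalization and poly-A control scaling (camera adjusted p of 2.9e-04 to 0.103 over its 18 alternatives). Cell wall genes were higher in 14 of 31 cases and lower in 3 (12 and 3 adjusted over the list alone, median 0.17), with UTR2 at 1.41. The cell wall call (camera adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation) ended without double-mutant replicate 2, without the dimmest 50% of probe sets and with quantile normalization (camera adjusted p of 0.012 to 0.591 over its 18 alternatives).

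In the double against the single mutant, limma called 2971 of 4398 probe sets (1397 higher, 1574 lower). Of these, 163 rose and 294 fell at least 2-fold, and arrays of the groups did not overlap for 70.8% of probe sets, where chance gives 10%. The count was 1930 without the dimmest 50% of probe sets. Median centring gave 1760 higher and 1173 lower, poly-A control scaling gave 1591 higher and 723 lower, and hybridization control scaling gave 1060 higher and 1744 lower.

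**Figure D3:**
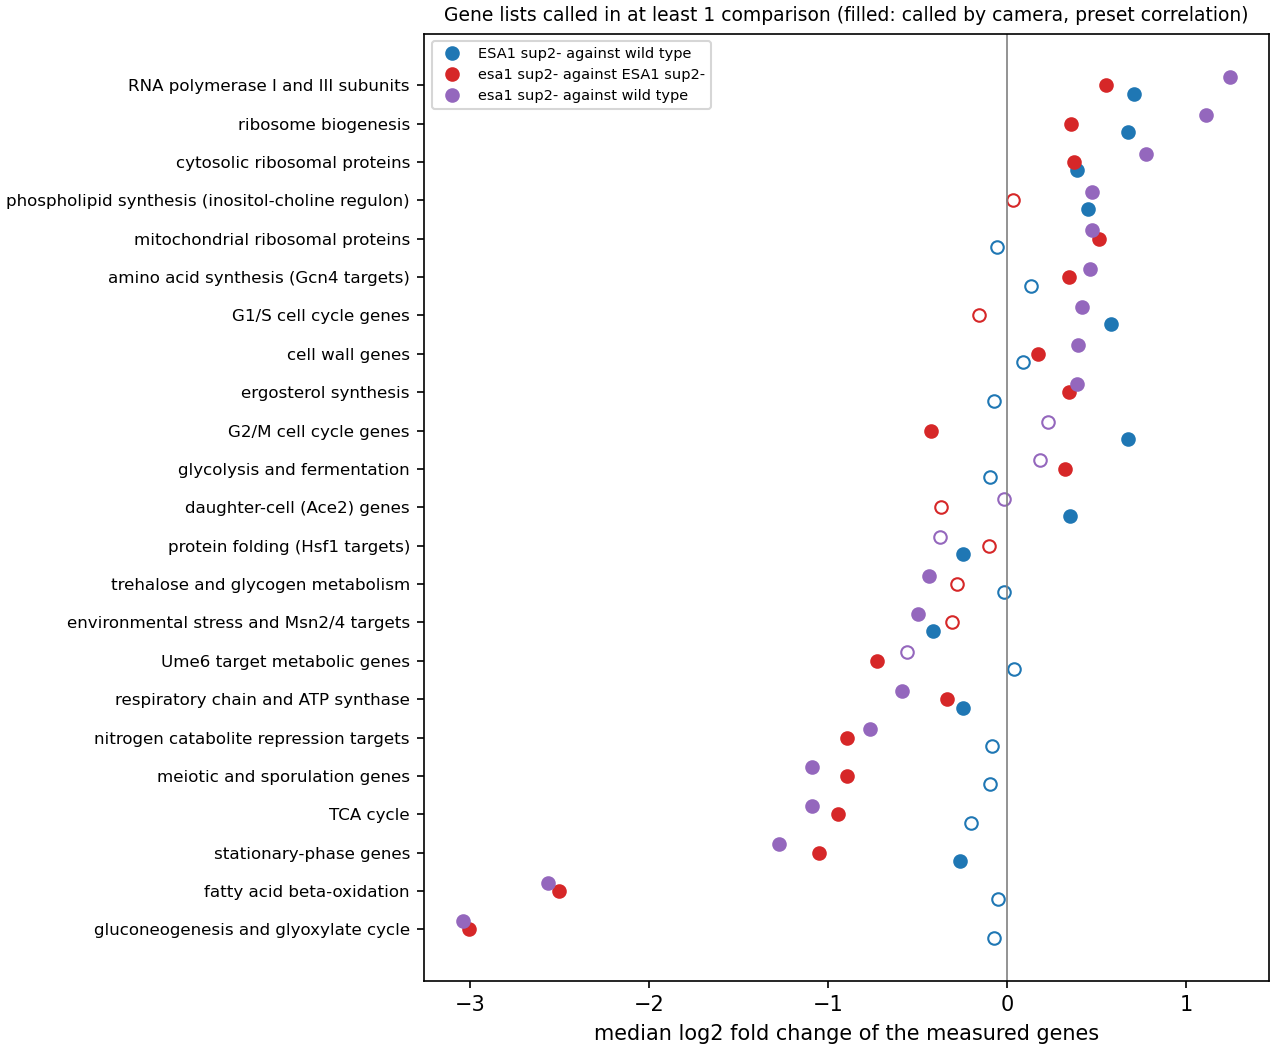
Median log2 fold change of each gene list called in at least 1 comparison, with 1 colour per comparison and filled points where camera called the list with the preset correlation. Gluconeogenesis and beta-oxidation lie at -3.04 and -2.56 in the double mutant against the wild type and at -0.07 and -0.05 in the single mutant against the wild type.

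Against the wild type, ribosome gene lists were higher in the double mutant and lists of non-sugar carbon use and stress were lower. HXT1 rose by 3.73 (SE 0.17, limma adjusted p = 2.3e-07), HXT2 by 3.68, TIR1 by 3.44, HUG1, ARI1 and the adenine deaminase gene AAH1 by 3.42 each, INA1 by 3.40 and TIR3 by 3.25. RGI2 was at -4.97 (SE 0.12, limma adjusted p = 1.3e-08), CIT3 at -4.74, SPS100 at -4.69, FDH1 at -4.65, SPG1 at -4.41, SSA3 at -4.35, ADY2 at -4.33 and PDH1 at -4.22. AAH1 had signals of 181 ± 12.5 (SD, n = 2) in the wild type, 977 ± 224 (SD, n = 3) in the single mutant and 3126 ± 532 (SD, n = 3) in the double mutant. DMC1 was lower than in the wild type (log2 fold change -0.44, limma adjusted p = 5.7e-04) and IME2 was higher (1.04). SLZ1 did not pass (-0.09, limma adjusted p = 0.46). Of 7 hexose transporter genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone). That list was not called (camera adjusted p = 0.31) except with poly-A control scaling (0.011 to 0.910 over 18 alternatives).

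Ribosome genes rose in the double mutant against the wild type. Of 83 ribosome biogenesis genes, 81 were higher and 1 lower (82 and 1 adjusted over the list alone). The median was 1.11 (camera adjusted p = 6.0e-17, adjusted p = 0.19 with an estimated correlation), and NSR1 went from 789 to 5779 and NOP1 from 562 to 4068. Of 128 cytosolic ribosomal protein genes, 125 were higher and none lower (126 adjusted over the list alone, median 0.78). Camera gave them an adjusted p of 1.1e-19 (adjusted p = 0.48 with an estimated correlation). Of 19 polymerase I and III subunits, 18 were higher (18 adjusted over the list alone, median 1.25, camera adjusted p = 9.7e-06, adjusted p = 0.19 with an estimated correlation). Mitochondrial ribosomal protein genes were higher in 46 of 70 cases and lower in 4 (46 and 4 adjusted over the list alone, camera adjusted p = 1.6e-04, adjusted p = 0.67 with an estimated correlation).

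Other biosynthetic and cell cycle lists rose in the double mutant against the wild type. Amino acid synthesis genes were higher in 27 of 46 cases and lower in 3 (27 and 3 adjusted over the list alone, camera adjusted p = 1.1e-03, adjusted p = 0.67 with an estimated correlation), with LEU9 at 2.45. Inositol-choline genes were higher in 12 of 19 cases and lower in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.19 with an estimated correlation), with PIS1 at 2.01. G1/S genes were higher in 18 of 29 cases and lower in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 7.4e-03, adjusted p = 0.67 with an estimated correlation), with ELO1, of fatty acid elongation, at 1.74. Both of these calls ended without the dimmest 50% of probe sets, with a camera adjusted p of 1.1e-03 to 0.052 for inositol-choline genes and 6.8e-04 to 0.059 for G1/S genes over 18 alternatives each. Cell wall genes were higher in 20 of 31 cases and lower in 5 (20 and 5 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.46 with an estimated correlation). Their call ended without double-mutant replicate 2 and with quantile normalization (camera adjusted p of 7.3e-03 to 0.220 over 18 alternatives). Ergosterol synthesis genes were higher in 15 of 26 cases and lower in 5 (15 and 5 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.62 with an estimated correlation). That call ended without wild-type replicate 1, any single-mutant array, or double-mutant replicate 1 or 2, and with quantile normalization, median centring and poly-A control scaling (camera adjusted p of 0.010 to 0.135 over 18 alternatives).

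Carbon and respiratory genes fell in the double mutant against the wild type. Gluconeogenesis genes were lower in 20 of 21 cases and higher in none (20 adjusted over the list alone, median -3.04, camera adjusted p = 6.7e-09, adjusted p = 0.21 with an estimated correlation). Beta-oxidation genes were lower in 19 of 20 cases and higher in 1 (19 and 1 adjusted over the list alone, median -2.56, camera adjusted p = 5.4e-08, adjusted p = 0.19 with an estimated correlation). Tricarboxylic acid cycle genes were lower in 17 of 18 cases (17 adjusted over the list alone, median -1.09, camera adjusted p = 4.9e-06, adjusted p = 0.27 with an estimated correlation). Respiratory genes were lower in 30 of 39 cases and higher in 2 (30 and 2 adjusted over the list alone, median -0.59, camera adjusted p = 1.2e-05, adjusted p = 0.62 with an estimated correlation).

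Stress, storage, nitrogen and meiotic genes also fell against the wild type. Stationary-phase genes were lower in 17 of 22 cases and higher in 1 (17 and 1 adjusted over the list alone, median -1.27, camera adjusted p = 1.2e-05, adjusted p = 0.19 with an estimated correlation). Stress genes were lower in 31 of 57 cases and higher in 5 (31 and 5 adjusted over the list alone, median -0.50, camera adjusted p = 2.6e-04, adjusted p = 0.62 with an estimated correlation). Nitrogen genes were lower in 16 of 19 cases and higher in 3 (16 and 3 adjusted over the list alone, median -0.76, camera adjusted p = 2.5e-03, adjusted p = 0.46 with an estimated correlation). Meiotic and sporulation genes were lower in 13 of 16 cases and higher in 2 (13 and 2 adjusted over the list alone, median -1.09, camera adjusted p = 5.0e-04, adjusted p = 0.19 with an estimated correlation). Only 16 of the 72 listed meiotic genes passed the filter on low signals, so these counts describe the brighter genes alone. Trehalose and glycogen genes were lower in 10 of 20 cases and higher in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.47 with an estimated correlation), with the trehalase gene ATH1 at -2.61. The trehalose call ended without wild-type replicate 2, single-mutant replicate 2, or double-mutant replicate 2 or 3, and with median centring, no filter, poly-A control scaling and the replicate block (camera adjusted p = 0.061 with the block). Over its 18 alternatives the camera adjusted p ran from 0.024 to 0.122.

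Limma called 3277 of 4398 probe sets in the double mutant against the wild type (1669 higher, 1608 lower). Of these, 524 rose and 506 fell at least 2-fold, and 81.8% of probe sets had arrays that did not overlap, where chance gives 20%. The count was 2092 without the dimmest 50% of probe sets, and the share of calls that were higher was 50.9%, against 68.5% with poly-A control scaling.

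The NuA4, Rpd3 and histone lists were not called. Of 12 measured genes of the NuA4 complex, ESA1 included, 5 were lower and 1 higher in the single mutant against the wild type (6 and 1 adjusted over the list alone, camera adjusted p = 0.19). In the double against the single mutant 7 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.13). In the double mutant against the wild type 7 were lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.067). That list was called lower with poly-A control scaling alone among 18 alternatives (camera adjusted p of 0.046 to 0.153). Of 11 measured genes of Rpd3 deacetylase complexes, 3 were higher and 1 lower in the single mutant against the wild type (3 and 1 adjusted over the list alone, camera adjusted p = 0.72). In the double mutant 1 was higher and 5 lower than in the single mutant (1 and 5 adjusted over the list alone, camera adjusted p = 0.13), and 3 were higher and 5 lower than in the wild type (3 and 5 adjusted over the list alone, camera adjusted p = 0.50). Histone genes were higher in 7 of 10 cases and lower in 2 in the double against the single mutant (7 and 2 adjusted over the list alone, camera adjusted p = 0.056). Histone genes were called higher there without single-mutant replicate 2, with no filter, with the replicate block and with hybridization control scaling (camera adjusted p of 0.011 to 0.241 over 18 alternatives). Against the wild type the double mutant's histone list was called with the last 3 of these settings (camera adjusted p of 0.027 to 0.299, and 0.067 as fitted). No a-specific mating gene passed the filter on low signals, whereas 5 alpha-specific genes did. The median, mean and camera direction differed in sign, none of them called, for meiotic, haploid-specific, histone and sulfur amino acid genes in the single mutant against the wild type and for strain markers in the double against the single mutant. The same held for glycolysis, sulfur amino acid, DNA damage and strain marker genes in the double mutant against the wild type.

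Both mutants were compared with the same wild-type arrays. Across 4398 probe sets their log2 fold changes correlated with r = 0.70, against 0.60 on average in 100 simulations of unchanged strains sharing those arrays, and probe sets are not independent replicates. The covariance was 0.336 against 0.00942 simulated, a difference of 0.326. The simulated unchanged strains shared 0.01 called probe sets on average, counted whatever the direction. Both mutants shared 978 probe sets called higher and 807 called lower, where independent lists of those sizes would share 476 and 356. Another 79 were higher in the single and lower in the double mutant, and 43 the reverse, where independent lists give 458 and 370. A split of the 2 wild-type arrays would leave 1 array to each mutant, so part of the excess of shared calls over independent lists may come from the shared controls.

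No chromosome was called in any comparison with all arrays. Chromosome XI was called higher in the double against the single mutant without double-mutant replicate 1 or without replicate 2 (median 0.18 and camera adjusted p = 0.13 with all arrays, 8.2e-03 to 0.912 over 18 alternatives). Fewer of its genes were called than of all probe sets. Of its 252 measured genes, 37 were higher, 26 lower and 189 not called in the single mutant against the wild type. There, 50.6% of all probe sets were called. In the double mutant 134 were not called against the single mutant and 105 against the wild type. Of all probe sets 67.6% and 74.5% were called in those comparisons. Chromosome XI was not called without double-mutant replicate 3. All 3 comparisons share 1 estimate of the spread, so a wide spread in 1 strain lowers the calls in each. Fewer calls thus need not mean smaller changes. The cause was not tested. The largest median of a chromosome in size was -0.27, on chromosome I in the double against the single mutant, and the lowest camera adjusted p of a chromosome was 0.13. Genes within 20 kb of a chromosome end were lower in the double mutant than in the wild type, with 44 of 68 lower and 13 higher and a median log2 fold change of -0.73 (camera adjusted p = 0.021, adjusted p = 0.88 with an estimated correlation). Among the 20 genes within 10 kb, 15 were lower and 3 higher, with a median of -1.60. The call ended without shared probe sets (median -0.52, camera adjusted p = 0.19) and without the dimmest 50% of probe sets (camera adjusted p = 0.45). It also ended without double-mutant replicate 1 (camera adjusted p = 0.052), wild-type replicate 1 (camera adjusted p = 0.105) or wild-type replicate 2 (camera adjusted p = 0.141), against 1.7e-06 to 0.448 over its 18 alternatives. The same genes were not called in the single mutant against the wild type (camera adjusted p = 0.31) or in the double against the single mutant (camera adjusted p = 0.13). They were called lower in both with no filter on low signals and with poly-A control scaling, with a camera adjusted p of 2.5e-05 to 0.907 and 6.6e-05 to 0.452 over 18 alternatives each.

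**Figure D4:**
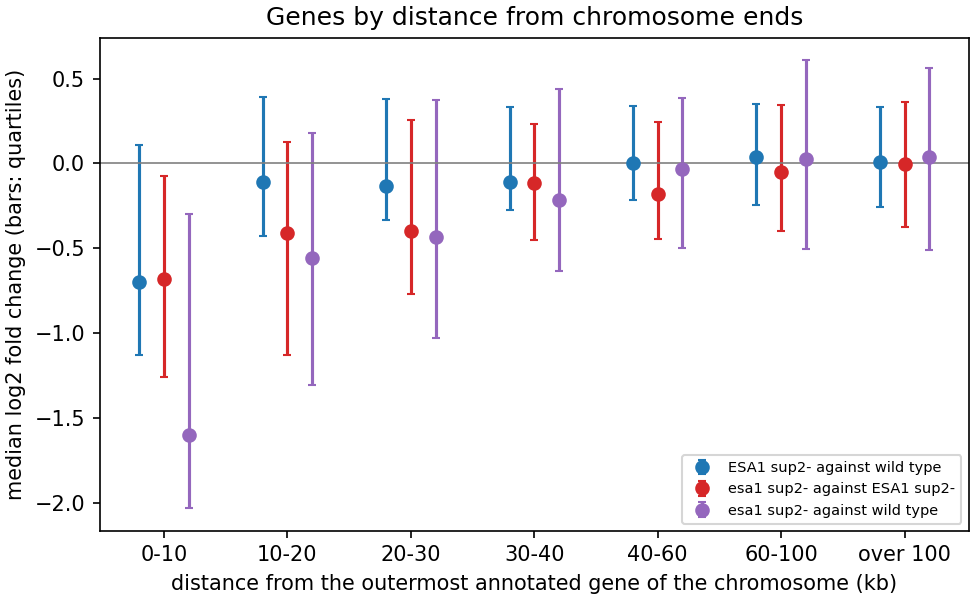
Median log2 fold change (points) with quartiles (bars) of genes by distance in kb from the outermost annotated gene of their chromosome, for the 3 comparisons. The 20 genes within 10 kb have medians of -0.70, -0.68 and -1.60, and the genes over 100 kb away have medians of 0.01, 0.00 and 0.04.

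RNA quality was read from the 3-prime to 5-prime log2 ratio of control genes, which was 1.11 ± 0.019 (SD, n = 2) in the wild type, 1.25 ± 0.021 (SD, n = 3) in the single mutant and 1.07 ± 0.084 (SD, n = 3) in the double mutant. All single-mutant arrays, on which ribosome genes and DMC1, SLZ1 and IME2 were higher than in the wild type, had higher ratios than the arrays of both other strains (exact two-sided permutation p = 0.1 in each case, the smallest these designs allow). Probe sets of ribosomal RNA had mean log2 signals of 8.89 and 9.53 in the wild type, 8.66, 8.63 and 8.73 in the single mutant and 7.61, 10.2 and 8.40 in the double mutant. They were lower on every single-mutant array than in the wild type (exact two-sided permutation p = 0.1, the smallest possible here), while the double mutant's spread covered both other strains (exact permutation p = 1 against the single mutant and 0.8 against the wild type). Poly-A control probe sets were lower on every double-mutant than single-mutant array, with a mean difference of -0.25 in log2 signal (exact two-sided permutation p = 0.1). They were also lower on every double-mutant array than on both wild-type arrays, with a mean difference of -0.30 (exact two-sided permutation p = 0.3). The median signal of S. cerevisiae probe sets was 586 ± 19.3 (SD, n = 2) in the wild type, 613 ± 0.0627 (SD, n = 3) in the single mutant and 549 ± 11.2 (SD, n = 3) in the double mutant, and the arrays of each pair of strains did not overlap (exact two-sided permutation p = 0.1 in each comparison). Wild-type replicates differed with an SD of 0.111 in log2 signal and single-mutant replicates 1 and 3 with 0.0900. Double-mutant replicates differed with 0.262 to 0.323.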

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

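The tests in this part were chosen after the results were seen. Probe sets outside the comparisons gave signals above the wild type. A reporter-construct probe set was at 8495, 9299 and 8093 in the double mutant and at or below 5.04 on all other arrays, at least 910-fold higher in the double mutant than in the wild type. Another 2 reporter probe sets were higher in the double mutant, with log2 fold changes of 1.14 (limma adjusted p = 0.011) and 2.20 (limma adjusted p = 0.012), and 2 were lower, at -0.63 (limma adjusted p = 5.0e-03) and -0.35 (limma adjusted p = 0.040). Probe sets named after the same sequence entry did not all move alike, and by their numbering they may read different parts of it. Other probe sets named after the entry of the one at 1.14 were at 1.29, 0.67, -0.46 and 0.28. They were not called (limma adjusted p of 0.079 to 0.904). The probe set at -0.63 is named after the same entry as the one that was at least 910-fold higher. Of 3470 probe sets with no gene listed, 26 were higher and 42 lower in the single mutant than in the wild type, and 38 were higher and 88 lower in the double mutant. Of 1746 probe sets of genes outside the S. cerevisiae table, 1 was higher and 1 lower in the double mutant, and 0 were higher and 2 lower in the single mutant. A probe set counted as higher also had to lie above background on every array of the mutant. Counts of lower probe sets had no such rule, so higher and lower counts cannot be set against each other.

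The fall of non-sugar carbon genes with the rise of ribosome genes in the double against the single mutant may have a technical or biological source. One scaling factor per array moves all lists alike, but the ribosome biogenesis and gluconeogenesis medians differed by 3.36 log2 units, which argues against it as the whole source. These lists were picked for that contrast, and the difference does not exclude scaling as a part of the smaller ribosome biogenesis rise (median 0.36). An earlier stage of the glucose-fed culture predicts that other glucose-repressed genes fall too. Read with no filter, 85.7% (6 of 7 measured) did, the exception being HXT7 (log2 fold change 0.20). Of all 5498 probe sets, 2031 were called lower with no filter. The 7 genes were chosen after the carbon lists were seen to fall. Any cause that lowers glucose-repressed genes gives the same result, so culture stage is not told apart from other causes. Culture density was not analysed here. The strains shared 0 fluidics stations, so a station effect cannot be told apart from the strain. The absence of ESA1 stays open as the biological explanation.

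The lower signals near chromosome ends in the double mutant against the wild type may likewise have several sources. For all 68 genes the median was -0.73 (quartiles -1.72 and 0.15). For the 50 genes read by unshared probe sets it was -0.52 (quartiles -1.44 and 0.21), a smaller shift over fewer genes, and 0% of 10000 random lists matched on mean signal were as low, though such lists do not allow for genes moving together. The camera call ended (adjusted p = 0.20 with these 50 genes set against all tested genes, 0.19 with shared probe sets left out throughout), which leaves shared signals open as a source. Of the 68 genes, 65 were not members of the lists that fell. These 65 genes had a median of -0.71 (quartiles -1.68 and 0.15) and were still called (camera adjusted p = 0.029). Leaving out so few genes could hardly change the result, so it shows only that most of the 68 genes lay outside those lists. The 65 genes were not run with an estimated correlation, with which all 68 were not called (camera adjusted p = 0.88).

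The difference of single-mutant replicate 2 from replicates 1 and 3 may come from the sample or the culture. RNA of the double mutant as a source is argued against by the reporter probe set, which gives a share of 0.0207%. A share of wild-type RNA was estimated at 7.37% over 272 genes, with quartiles of -3.81% and 24.8%, which leaves it open. A different oxygen supply predicts lower hypoxic genes, and 14 genes linked to oxygen supply other than ANB1, TIR1 and TIR3 were read. Their median deviation from the mean of replicates 1 and 3 was -0.33 in replicate 2, as low as in 0% of 10000 random lists. Such lists do not allow for genes moving together, and the deviation is that of 1 array, so this share is no chance level. Of the 14, 4 were above that mean (ROX1 by 0.33, OLE1 by 0.19, FET4 by 0.18 and HMG2, which was below replicate 3, by 0.10). ROX1 and MOT3 (-0.01), both among the 14, encode repressors of hypoxic genes, so a fall was not predicted for them. COX5B was at 425 against 897 and 893, which is consistent with a different oxygen supply, and no biological group in the design separates these arrays.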

How the results depend on the processing

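Control-probe scaling and the removal of shared probe sets were chosen after seeing the data. No named gene, called list or chromosome-end shift that was called reversed under any alternative run. Over all called probe sets 1 did, that of RGI1 with quantile normalization in the double against the single mutant (log2 fold change 0.15, limma adjusted p = 0.036, against -0.11 and 0.036). The calls of genes in the single mutant against the wild type (2227) were 1377 without the dimmest 50% of probe sets, where fewer were tested, and 1228 with poly-A control scaling, and 1406 to 2516 with 1 array left out (1436 without wild-type replicate 1). In the double against the single mutant (2971) they were 1930 without the dimmest 50% and 2586 to 2986 with 1 array left out, and in the double mutant against the wild type (3277) 2092 and 2818 to 3334. Shared calls of both mutants (1785) were 1135 without the dimmest 50%, 1015 with poly-A control scaling and 1168 to 1975 with 1 array left out, and their correlation was 0.68 to 0.70. ESA1 in the single mutant was -0.31 with poly-A control scaling and -0.44 to -0.27 with 1 array left out. With an estimated correlation 0 lists were called in each comparison, against 11, 17 and 18, and 0 regions. With 1 array left out 9 to 12, 16 to 19 and 15 to 18 lists were called. The chromosome-end call in the double mutant against the wild type (1 region) became 0 without the dimmest 50% or shared probe sets, while 1 region was called in the single mutant against the wild type and in the double against the single mutant with no filter and with poly-A control scaling. With 1 array left out, 0 to 1 region was called in both comparisons of the double mutant and 0 in the single mutant. In the double against the single mutant that region was chromosome XI, called higher, and not the chromosome ends. Except where fewer probe sets were tested, the cause was not tested. Scaling moved the median of all genes to 0.28 (poly-A) in the double mutant against the wild type, and to 0.19 (poly-A), -0.13 (hybridization controls) and 0.11 (median centring) in the double against the single mutant, while no called list's median changed sign. With 1 wild-type array left, that array is assumed to vary like the other groups. Poly-A control levels were lowest on double-mutant replicate 1, at -0.48 on the log2 scale relative to the mean of the arrays. With that scaling the prior degrees of freedom of limma were 26618, against 3.76 without it, so its p-values reflect a spread shared by probe sets and hardly a gene's own arrays. Same-numbered arrays did not deviate together (r from -0.09 to 0.14), and with the replicate block 2033, 2894 and 3196 genes were called. Some lists were called under an alternative alone. In the single mutant against the wild type these were haploid-specific, glycolysis, gluconeogenesis and nitrogen genes. In the double against the single mutant they were histone, alpha-specific, phosphate, stress, hexose transporter, proteasome, silencing, sulfur amino acid, daughter-cell and other acetyltransferase and deacetylase genes. In the double mutant against the wild type they were NuA4, histone, Ume6 metabolic, alpha-specific, protein folding, glycolysis and hexose transporter genes. The replicate block made the histone call in both comparisons of the double mutant and ended that of trehalose genes. Signals near background limit dim genes most.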

Other observations

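The tests and genes in this part were chosen after values were seen. BNA4 and BNA6, enzymes of NAD synthesis, and TNA1 were lower in both mutants than in the wild type, and other genes of that pathway were not tallied. BNA4 was at 1820 ± 100 (SD, n = 2) in the wild type, 524 ± 60.2 (SD, n = 3) in the single mutant and 121 ± 28.9 (SD, n = 3) in the double mutant, BNA6 at 2634, 1184 and 256, and the nicotinic acid transporter gene TNA1 at 2725, 782 and 271 (limma adjusted p of 1.3e-04 or less for each mutant against the wild type). UME6, which encodes a repressor of early meiotic genes, was at 376 ± 28.6 (SD, n = 2) in the wild type, 918 ± 74.0 (SD, n = 3) in the single mutant and 754 ± 105 (SD, n = 3) in the double mutant, higher than in the wild type in both (limma adjusted p of 1.3e-04 and 1.7e-04). LEU2 was at 821, 734 and 1997, higher in the double mutant than in the single mutant (limma adjusted p = 3.4e-05).

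A hypothesis from DMC1, SLZ1 and IME2 was that early meiotic genes rise as a group in the single mutant. Of 22 other early meiotic genes, all of them on the fixed meiotic list and read here with no filter on low signals, 14 (63.6%) were called higher than in the wild type and 0 lower, with a median log2 fold change of 0.50 (quartiles 0.10 and 1.06), which is consistent with it. SPO13, HOP1, SPO11 and SPO16 were at 1.23, 1.22, 1.35 and 1.57 (limma adjusted p of 3.6e-05 or less). Of all genes 25.9% were called higher with no filter. The other 49 members of the fixed list, DMC1 and IME2 included, were more often lower, with 6 higher and 27 lower with no filter and a median of -0.29. The fixed list as a whole does not share the direction, with 20 of 71 genes higher and 27 lower with no filter (camera adjusted p = 0.17), and it was not called with the filter either (16 genes, camera adjusted p = 0.72). A second hypothesis was that SUP2 is a gene whose transcript is lost. No gene above 50 signal units on both wild-type arrays was at background on all 6 sup2- arrays (0 genes), which argues against the loss of a transcript measured here and leaves other kinds of mutation open.

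Other splits of the 6 mutant arrays were counted. The real split of the double and single mutants called 2764 genes in a fit of these arrays alone, and the highest other split called 0. For gene lists the real split called 17 and the highest other 16. In both cases 1 of the 10 splits reached the real value, and 10 splits are too few for a share under 0.05. Each other split sets 2 arrays of 1 strain and 1 of the other against the reverse, so it keeps part of the strain difference and is no reference without one.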
